A study of Mus musculus with 12 samples.

How the data were processed

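RNA was sequenced from bone-marrow-derived dendritic cells and from exosomes of the same cultures, from 6 mice. Per the labels' protocols, marrow from C57Bl/6 femurs was cultured for 7 days in DMEM with 10% fetal calf serum and 10% supernatant of X-63 cells, which contains GM-CSF. Exosomes were collected from the culture medium by ultrafiltration and differential ultracentrifugation. RNA of the cells was extracted with Tri-Reagent, whereas RNA of the vesicles was extracted with Trizol LS and purified on a Qiagen kit, so the extraction method and the compartment cannot be told apart. Serum and the X-63 supernatant are further sources of vesicles, and whether either was cleared of vesicles is not given in the sources used here. Libraries were made from 200 ng of total RNA with a TruSeq kit and read as 80 bp paired ends on a NextSeq instrument, per the labels' protocols.

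The deposited values are whole-number counts per gene with 1 length per gene. Per the submitters' processing notes, the authors used featureCounts and the mouse build mm10. The aligner, the versions, the annotation and the strand setting are not given in the sources used here. Reads of overlapping genes on opposite strands therefore cannot be separated, and counts of genes with near-identical copies are uncertain. The tables of the 12 libraries held the same values as the table of the series. Symbols and coordinates (GRCm38, the assembly of mm10) were matched by gene identifier for 25275 of 27179 identifiers. The other 1904 stayed unnamed and took 1.06% to 2.02% of the counts of a cell library and 2.31% to 7.88% of those of an exosome library, with 95% Wilson intervals at most 0.029 points to either side.

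Groups, sex and mouse number were taken from the labels. Each of the 4 groups had 3 libraries, each from a different mouse. The WT mice were 2 females and 1 male and the mice labelled Sidt1/Sidt2 double knock-out (DKO) were 3 males, so genotype was partly confounded with sex. Because Sidt1 counts went against the DKO label, the libraries are called by their label throughout. No pair of libraries of a group agreed within sampling noise. Total counts ran from 7215083 to 32273898 per library, so 3 counts, the limit that a count of 0 allows, stood for 0.093 to 0.416 CPM, counts scaled to the size of the library. Intervals and limits of this kind cover counting error only.

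The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) on the deposited counts. It used robust fits, the package's filter on low counts by group, TMM scaling and Benjamini-Hochberg adjustment over all genes tested, and genes with an adjusted p below 0.05 are referred to as called. Each pairwise comparison was fitted on its own 6 libraries and the compartment by genotype interaction on all 12. Levels are TMM-normalised CPM, given as mean ± SD over 3 libraries, and log2 fold changes are given ± SE. Gene lists, 37 in all, were written down before the data were examined. The 36 lists with at least 3 tested genes were tested with camera (limma 3.58.1), which asks whether the genes of a list rank apart from all others, with a preset correlation of 0.01 and again with an estimated correlation, and adjusted over lists. Shares of counts were compared between compartments by an exact sign-flip permutation test over the 6 mice and between genotypes by an exact permutation test of 3 against 3, both two-sided. Relations with the deposited gene length were Spearman correlations across genes, which are not independent replicates. GC content came from GENCODE transcripts of the same build and was known for 24390 genes. List medians were also computed after taking off the median of genes of like length and GC content, a step added after seeing the data.

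Genes were named by a rule written before the data were examined. It took Sidt1 and Sidt2, then the 12 called genes with the largest change in each direction among those with a mean log2 CPM above 1, libraries that did not overlap and a symbol that is not a predicted gene. To these it added up to 4 members per list with the smallest p, sex-linked genes, called genes near Sidt1 or Sidt2, and the 5 most abundant genes per group. Some results of single genes that the rule named are not reported here.

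A mouse's number marks both of its libraries, so the numbers pair cells with exosomes. The deviations of the 2 libraries of a mouse from their group means correlated at 0.006, 0.078, 0.102, 0.147, 0.116 and 0.114 for mice 33, 42, 46, 151, 152 and 153, and for 6 of 6 cell libraries the best match was the exosome library of the same mouse. The fit with the mouse as a block was an alternative. Other alternatives were DESeq2 size factors, total-count scaling, removal of mitochondrial and the 20 most abundant genes, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma voom with quality weights, a fit on all 12 libraries, sex as a covariate, and each library left out in turn. With sex as a covariate the WT side rests on the single male, mouse 46, which is assumed to vary like the other mice. Leaving out both libraries of mouse 33, chromosome 9, or Sidt1 and Sidt2 (from counts or from lists) was added after seeing the data.

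The test was first run on simulated counts drawn from the real means and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold. It recovered 39% and 95% of these for WT exosomes against WT cells (12615 genes), 87% and 100% for exosomes against cells labelled DKO (12120 genes), 92% and 100% for cells labelled DKO against WT cells (12966 genes), 38% and 91% for exosomes labelled DKO against WT exosomes (11853 genes) and 22% and 88% for the interaction (12780 genes). In the same order 8, 16, 19, 13 and 8 unchanged genes were called, which is 5.6%, 7.9%, 9%, 9.2% and 6.8% of the calls against a nominal 5%. The changed genes were picked above a floor of mean CPM, so recovery at lower counts was not measured. Tables and figures were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.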

Results

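Gene expression was profiled in bone-marrow-derived dendritic cells, antigen-presenting cells grown from marrow with the growth factor GM-CSF, and in exosomes, small vesicles that cells release, collected from the medium of the same cultures. The 12 libraries formed 4 groups of 3: cells and exosomes of wild-type (WT) mice 33, 42 and 46, and cells and exosomes of mice 151, 152 and 153, labelled double knock-out for Sidt1 and Sidt2. These genes encode relatives of the nematode double-stranded RNA transporter SID-1. Total counts were 19095284 to 32273898 in WT cells, 9008189 to 31651403 in cells labelled DKO, 8200062 to 22236435 in WT exosomes and 7215083 to 16348101 in exosomes labelled DKO. The design called for differential expression between all groups. The first principal component, 59.4% of the variance of the 1000 most variable genes, separated exosomes from cells. On the second, 16.6%, the WT exosomes of mouse 33 lay at 57.06 and the other libraries between -26.75 and 12.67.

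Sidt2 was nearly absent from the libraries labelled DKO, whereas Sidt1 was present in them and nearly absent from the WT libraries. Sidt2 (GRCm38 chromosome 9, 45937857 to 45958000) stood at 217, 169 and 173 CPM in WT cells and at 1.32, 0.632 and 1.14 CPM in cells labelled DKO. In exosomes it stood at 323, 299 and 218 CPM in WT and 0.992, 0.857 and 2.39 CPM in the libraries labelled DKO. It fell by 7.67 ± 0.23 on the log2 scale in cells (edgeR, adjusted p = 1.55e-08) and by 7.76 ± 0.39 in exosomes (adjusted p = 0.000149). Sidt1 (GRCm38 chromosome 16, 44240177 to 44333212) had 3, 0 and 0 counts in WT cells against 594, 1722 and 574 in cells labelled DKO, where it reached 52.4, 51.8 and 59.5 CPM. In exosomes it had 0, 3 and 4 counts in WT and 483, 440 and 309 counts, or 34.2, 29.0 and 41.1 CPM, in the libraries labelled DKO. The ratio of DKO to WT in counts per total was 1560 in cells (95% counting interval 534 to 7570) and 190 in exosomes (92.1 to 475), with adjusted p = 2.07e-08 and 0.000844. The Sidt1 counts thus ran against the label, and every genotype direction below is between libraries labelled DKO and WT. Counts per gene do not show which exons the reads came from, and which parts of the genes were targeted is not given in the sources used here. The sex labels matched the counts. Xist, expressed from the inactive X chromosome, stood at 134 and 206 CPM in cells of the female mice 33 and 42 and at no more than 0.353 CPM in the other cell libraries. The Y-linked Ddx3y stood at 63.6 CPM in cells of the male WT mouse 46 and at 59.3 to 77.4 CPM in cells labelled DKO.

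**Figure D1:**
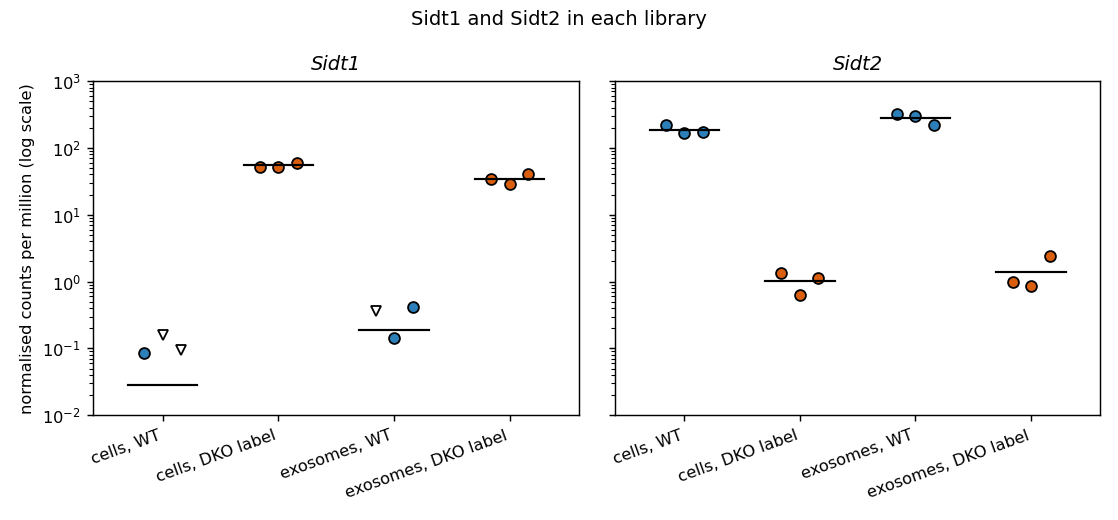
Normalised CPM of Sidt1 and Sidt2 in each of the 12 libraries on a log axis, with filled circles for values, open triangles at the 3-count limit for libraries with 0 counts, and black lines for group means. Sidt2 is low in the 6 libraries labelled DKO (0.632 to 2.39 CPM) and Sidt1 is low in the 6 WT libraries (0 to 4 counts).

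Exosomes were set against the cells that released them to see which transcripts the vesicles held in excess or in deficit. In WT mice, transcripts of mature dendritic cells were far lower in exosomes. Ccr7, the receptor that guides dendritic cells to lymph nodes (GRCm38 chromosome 11, 99144199 to 99155077), fell from 807 ± 85.6 CPM in cells to 36.2 ± 3.06 CPM in exosomes (SD, n = 3; log2 fold change -4.46 ± 0.17, edgeR adjusted p = 8.03e-05). The maturation marker Cd83 fell from 376 ± 14.1 to 32.1 ± 4.98 CPM, the chemokine Ccl22 from 2110 ± 259 to 338 ± 42.6 CPM, and Il12b, a subunit of interleukin 12, from 33.2 ± 2.28 to 1.37 ± 0.809 CPM. Anxa2, which encodes the membrane-binding protein annexin A2, rose from 727 ± 80.3 to 4350 ± 803 CPM (log2 fold change 2.60 ± 0.19, adjusted p = 0.000363). Of 24 dendritic cell markers tested, 17 fell and 1 rose, and the same counts held adjusted over the list alone (median log2 fold change -1.63, camera adjusted p = 9.32e-14, adjusted p = 0.0887 with an estimated correlation).

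Antigen presentation genes were lower in WT exosomes as well. Of 13 genes of MHC class II presentation, which loads peptides for helper T cells, 7 fell and 0 rose, with 9 falling adjusted over the list alone (camera adjusted p = 0.000456, adjusted p = 0.466 with an estimated correlation). Among them H2-Ab1 fell from 1790 ± 168 to 624 ± 60.6 CPM, the invariant chain Cd74 from 6000 ± 1010 to 1970 ± 274 CPM, and Ciita, the master regulator of the class, by 2.02 on the log2 scale. For MHC class I presentation, 14 of 21 genes fell and 1 rose, also adjusted over the list alone (adjusted p = 1.59e-05, adjusted p = 0.205 with an estimated correlation), among them the chaperone Canx (log2 fold change -1.51) and H2-Q6 (-3.07), whose reads may be shared with other H2-Q genes. Markers of macrophages, which also grow in these cultures, went the same way: 9 of 20 fell and 3 rose, also adjusted over the list alone (adjusted p = 0.0405, adjusted p = 0.466 with an estimated correlation). Csf1r, the receptor for macrophage colony-stimulating factor, fell from 710 ± 99.0 to 183 ± 32.5 CPM and the mannose receptor Mrc1 by 1.76 on the log2 scale. Over its alternatives the macrophage list ran from adjusted p = 0.0047 to 0.0798, and it lost its call without the exosomes of mouse 33 (0.0592).

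Cell cycle transcripts and those for spliceosome and nuclear RNA-binding proteins were also low in WT exosomes. Of 37 cell cycle genes 17 fell and 1 rose, also adjusted over the list alone (adjusted p = 1.59e-05, adjusted p = 0.466 with an estimated correlation). Top2a, the topoisomerase of dividing cells, fell from 202 ± 39.1 to 34.6 ± 4.84 CPM and the kinetochore motor Cenpe by 3.91 on the log2 scale. Of 74 spliceosome and nuclear RNA-binding genes 29 fell and 6 rose, or 33 and 6 adjusted over the list alone (adjusted p = 0.00761, adjusted p = 0.594 with an estimated correlation), with the splicing coactivator Srrm2 at -2.09 ± 0.15. Taking off the median of genes of like length and GC content moved that list from -0.45 to -0.25. Of 25 heat shock and immediate early genes 9 fell and 3 rose, also adjusted over the list alone (adjusted p = 0.00287, adjusted p = 0.466 with an estimated correlation), with Egr1 falling from 224 ± 13.1 to 33.7 ± 7.60 CPM. That list lost its call without both libraries of mouse 33 (0.0586, the highest of a range from 9.44e-05). The nuclear long non-coding RNA Neat1 fell by 1.68 ± 0.23, and Malat1, which stays in the nucleus, by 3.77 ± 0.92 (adjusted p = 0.0159). Malat1 lost its call without the WT exosomes of mouse 33 (adjusted p = 0.146) and without the cells of mouse 42 (0.0539), within a range of 0.000323 to 0.218 over its alternatives. The list of long non-coding RNAs, with 11 tested, was not called (median 0.18, mean -0.67, camera adjusted p = 0.634). It does not hold nuclear RNAs alone, since Norad, found in the cytoplasm, is on it.

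Transcripts of ribosomal proteins and of the nuclear-encoded respiratory chain were higher in WT exosomes. Of 85 cytosolic ribosomal protein genes 45 rose and 0 fell, or 49 adjusted over the list alone (median log2 fold change 1.10, camera adjusted p = 6.68e-10, adjusted p = 0.624 with an estimated correlation). Of 83 nuclear genes of oxidative phosphorylation, the mitochondrial pathway that makes ATP, 59 rose and 0 fell, or 63 adjusted over the list alone (median 0.97, adjusted p = 9.09e-13, adjusted p = 0.466 with an estimated correlation). Of 77 mitochondrial ribosomal protein genes 40 rose and 0 fell, or 46 adjusted over the list alone (median 0.59, adjusted p = 2.93e-08, adjusted p = 0.466 with an estimated correlation). Of 13 protein-coding genes of the mitochondrial genome 0 were called, also adjusted over the list alone (median 0.28, mean -0.03, adjusted p = 0.967). Rps2 rose from 156 ± 69.9 to 1300 ± 542 CPM, with reads that pseudogenes can share, Cox8a by 1.70, Ndufa13 by 1.53 and Mrps24 by 1.56 on the log2 scale. In the WT exosomes of mouse 33, ribosomal protein genes took 4.26% of counts (95% Wilson interval 4.248 to 4.275), against 2.43% (2.420 to 2.433) and 1.70% (1.697 to 1.712) in those of mice 42 and 46. The ribosomal protein median was 0.61 without the WT exosomes of mouse 33 and 0.45 without both libraries of that mouse, within 0.45 to 1.33 over its alternatives. Taking off the median of genes of like length and GC content lowered the medians to 0.38 for ribosomal proteins, 0.20 for oxidative phosphorylation and 0.12 for mitochondrial ribosomal proteins. Of 20 replication-dependent histone genes 9 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.0157, adjusted p = 0.466 with an estimated correlation), among them H2ac18 (log2 fold change 2.40 ± 0.44). The histone list ran from adjusted p = 0.000318 to 0.114 over its alternatives and lost its call without the exosomes of mouse 46 (0.114). Of 27 autophagy genes 11 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.0465, adjusted p = 0.466 with an estimated correlation), among them Pik3c3, the lipid kinase that starts autophagosomes, which rose from 34.5 ± 0.961 to 165 ± 42.4 CPM, and Gabarap (1.14). The autophagy list ran from 0.0145 to 0.131 over its alternatives. It lost its call with the mouse as a block (0.0545), with total-count scaling (0.101), with a filter of 1 CPM (0.052), in the fit on all 12 libraries (0.0856), without the cells of mouse 42 (0.0781) or 46 (0.0792), and without the exosomes of mouse 46 (0.131). The list of extracellular vesicle machinery was not called (6 of 31 rose, 3 fell, adjusted p = 0.124).

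Across all 12829 genes tested, 4909 were called in WT exosomes against WT cells, 2400 higher and 2509 lower, with 1279 and 1632 of these at least 2-fold changed. The 3 libraries of one group lay entirely above the other for 55.4% of genes, where chance gives 10%. Under total-count scaling the median of all genes went from -0.015 to -0.387 and 1114 genes were higher and 4134 lower, so the directions above are relative to the typical gene. The count was 2471 without the cells of mouse 42, 2284 without those of mouse 46 and 3064 without the exosomes of mouse 42. Among the largest increases were those of Fam168b (151 ± 13.7 to 2830 ± 2170 CPM), Wsb2 (126 ± 15.5 to 1890 ± 1220 CPM), Metrn (9.76 ± 1.96 to 172 ± 136 CPM), Rap1gap2 and Rnf144a. These 5 genes lost their calls without both libraries of mouse 33, at adjusted p = 0.0538 to 0.111, while their lowest value over the alternatives was 6.31e-14 for Wsb2.

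The same comparison was made in the mice labelled DKO. Ccr7 fell from 696 ± 186 CPM in cells to 22.9 ± 3.90 CPM in exosomes (SD, n = 3; log2 fold change -4.92 ± 0.23, edgeR adjusted p = 2.49e-07), Cd83 from 324 ± 71.3 to 18.5 ± 2.88 CPM and Dpp4, a cell surface peptidase of dendritic cells, with a log2 fold change of -4.55 ± 0.21. Of 23 dendritic cell markers 19 fell and 1 rose, also adjusted over the list alone (median -2.01, camera adjusted p = 3.41e-19, adjusted p = 0.321 with an estimated correlation). Of 13 MHC class II genes 11 fell and 0 rose, also adjusted over the list alone (median -1.70, adjusted p = 4.55e-09, adjusted p = 0.321 with an estimated correlation), with H2-Ab1 falling from 1430 ± 227 to 382 ± 39.6 CPM and Cd74 from 4230 ± 577 to 1230 ± 27.6 CPM. Of 21 MHC class I genes 14 fell and 0 rose, also adjusted over the list alone (adjusted p = 9.03e-06, adjusted p = 0.335 with an estimated correlation), among them the peptide transporter Tap1 (log2 fold change -1.77). Of 20 macrophage markers 12 fell and 2 rose, also adjusted over the list alone (adjusted p = 0.0118, adjusted p = 0.616 with an estimated correlation), among them Csf1r (-1.70) and the complement gene C1qa (-1.60).

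Nuclear RNAs and the mitochondrial genome were low in exosomes labelled DKO. Malat1 fell from 310 ± 42.8 to 5.15 ± 0.750 CPM (log2 fold change -5.93 ± 0.17, adjusted p = 9.69e-09) and Neat1 from 180 ± 19.5 to 38.1 ± 4.80 CPM, whereas Norad, a long non-coding RNA found in the cytoplasm, rose by 0.71 ± 0.11. Of 10 long non-coding RNAs on the list 6 fell and 1 rose, also adjusted over the list alone (adjusted p = 0.000198, adjusted p = 0.321 with an estimated correlation). Of 13 protein-coding genes of the mitochondrial genome 8 fell and 0 rose, also adjusted over the list alone (median -1.05, adjusted p = 0.00641, adjusted p = 0.634 with an estimated correlation). ND5 fell from 5110 ± 353 to 886 ± 673 CPM. It overlaps ND6 on the opposite strand, so reads within the overlap cannot be told apart. In the fit on all 12 libraries the mitochondrial list lost its call (camera adjusted p = 0.0909, within 1e-07 to 0.0909 over its alternatives). ND5 lost its call there too (edgeR adjusted p = 0.0635). The mitochondrial ribosomal RNA mt-Rnr2 fell by 2.51 on the log2 scale. Of 37 cell cycle genes 22 fell and 1 rose, or 22 and 2 adjusted over the list alone (adjusted p = 0.000198, adjusted p = 0.616 with an estimated correlation), with Top2a falling from 157 ± 29.1 to 31.7 ± 6.87 CPM. Of 74 spliceosome genes 39 fell and 9 rose, also adjusted over the list alone (adjusted p = 0.00613, adjusted p = 0.616 with an estimated correlation). Taking off the median of genes of like length and GC content left -0.20 of the spliceosome median of -0.38.

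Of the groups that were higher in WT exosomes, oxidative phosphorylation and mitochondrial ribosomal proteins also rose in exosomes labelled DKO. Respectively 39 of 82 and 33 of 77 genes rose and 5 and 3 fell (adjusted p = 0.000198 and 0.0047, adjusted p = 0.727 for both with an estimated correlation), with 40 and 33 rising adjusted over the list alone. The correction for length and GC content took their medians from 0.39 to 0.13 (the 79 genes with a known GC content) and from 0.29 to 0.03. Atp5d, a subunit of ATP synthase, rose from 42.9 ± 4.62 to 217 ± 28.1 CPM. Cytosolic ribosomal protein genes were divided, with 31 of 85 rising and 10 falling, also adjusted over the list alone (median 0.13, adjusted p = 0.0232, adjusted p = 0.752 with an estimated correlation). Without the exosomes of mouse 152 (0.153) and in the fit on all 12 libraries (0.0576) this list lost its call (within 0.00237 to 0.153 over its alternatives). After the correction for length and GC content its median was -0.14. Of 17 histone genes 7 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.0214, adjusted p = 0.321 with an estimated correlation), with H2ac19 at 2.74 ± 0.28, and the list lost its call with no filter on low counts (0.0711, the highest of a range from 0.0121). Of 27 autophagy genes 13 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.0270, adjusted p = 0.321 with an estimated correlation), among them Tecpr1 (1.56) and Map1lc3a (1.30). Of 25 heat shock and immediate early genes 10 fell and 2 rose, also adjusted over the list alone (adjusted p = 0.0270, adjusted p = 0.616 with an estimated correlation), and Jund rose by 1.97. That list ran from 0.00538 to 0.086 over its alternatives and lost its call without the exosomes of mouse 151 (0.086) or 152 (0.0711). Diaph1, an actin nucleator, rose from 233 ± 4.07 to 2340 ± 423 CPM (log2 fold change 3.33 ± 0.16, adjusted p = 3.10e-07) and Anxa2 from 819 ± 83.7 to 5330 ± 987 CPM. Sema7a (-5.58) and Ceacam15 (-6.03), which encode surface proteins, were among the largest decreases.

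In this comparison 5844 of 12316 genes were called, 2922 higher and 2922 lower, of which 1029 and 1405 were at least 2-fold changed. Groups did not overlap for 58.4% of genes, where chance gives 10%. Total-count scaling moved the median of all genes from -0.012 to -0.144 and gave 2214 higher and 3433 lower.

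**Figure D2:**
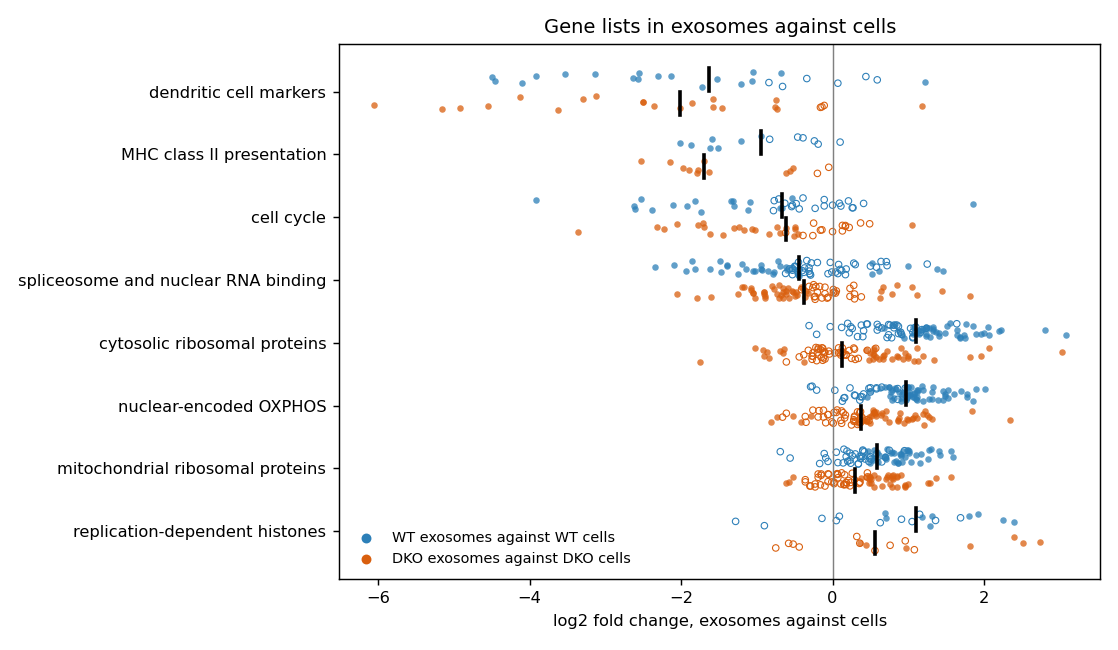
Log2 fold changes of exosomes against cells for the tested members of 8 gene lists, each point a gene and each black line a median, in WT mice (blue) and mice labelled DKO (orange), with filled points for called genes. Medians of dendritic cell markers lie at -1.63 and -2.01, and those of cytosolic ribosomal proteins at 1.10 and 0.13.

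Whether the exosome-to-cell difference depended on genotype was tested as an interaction. No gene passed: 0 of 12970 genes were called by edgeR, 776 had an unadjusted p below 0.05 and the smallest adjusted p was 0.715. DESeq2 called 0 genes and limma voom with quality weights 163. Of the 36 gene lists 11 passed the camera test, each toward a lower exosome-to-cell change in the libraries labelled DKO. The cytosolic ribosomal proteins had a median interaction of -0.90 (camera adjusted p = 1.37e-26, adjusted p = 0.577 with an estimated correlation). Among them Rpl34 was estimated at -1.69 ± 0.50 and Rps23 at -1.22 ± 0.40 (adjusted p = 0.715 for both, range 0.0388 to 1.0 over the alternatives of Rpl34). Oxidative phosphorylation had a median of -0.49 (adjusted p = 1.66e-15, adjusted p = 0.591 with an estimated correlation), with Atp5e at -0.93 ± 0.30, and mitochondrial ribosomal proteins a median of -0.24 (adjusted p = 5.62e-06, adjusted p = 0.72 with an estimated correlation). Dendritic cell markers had a median of -0.44 (adjusted p = 0.000136, adjusted p = 0.423 with an estimated correlation), with Clec10a, a lectin, at -0.76 ± 0.21. In each of these 4 lists the count of called genes was 0, over all genes and adjusted over the list alone. Without the WT exosomes of mouse 33 the ribosomal protein median was -0.38 (adjusted p = 8.18e-16). The interaction itself went with gene length (Spearman 0.259 across genes, median -0.26 in the fifth of shortest genes and 0.16 in that of the longest). Taking off the median of genes of like length and GC content left -0.51 for ribosomal proteins, -0.20 for oxidative phosphorylation, -0.06 for mitochondrial ribosomal proteins and -0.44 for dendritic cell markers. The 3 libraries' differences did not overlap between genotypes for 13.2% of genes, where chance gives 10%, and total-count scaling moved the median of all genes from 0.026 to 0.254.

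Cells labelled DKO were set against WT cells to see the effect of the genotype in the cells. Apart from Sidt1 and Sidt2, the clearest differences were in Cadm1, which encodes a cell adhesion molecule, and Wdfy1, which encodes an endosomal protein linked to Toll-like receptor signalling. Cadm1 (GRCm38 chromosome 9, 47530170 to 47862280) had 3, 3 and 6 counts in WT cells and 151, 491 and 116 in cells labelled DKO, a ratio of 102 (95% counting interval 58.3 to 199; edgeR adjusted p = 2.26e-07). Wdfy1 (GRCm38 chromosome 1, 79702262 to 79776143) rose from 10.1 ± 1.60 to 75 ± 8 CPM (SD, n = 3; log2 fold change 2.91 ± 0.15, adjusted p = 1.23e-06). The fatty acid binding protein gene Fabp4 rose from 58.3 ± 2.78 to 135 ± 17.1 CPM (adjusted p = 0.00112), the cytokine Il18 from 8.21 ± 0.872 to 22.7 ± 3.08 CPM (0.00218), and Nnt, which encodes the mitochondrial transhydrogenase (GRCm38 chromosome 13, 119335527 to 119409257), from 13.6 ± 1.35 to 34.7 ± 5.92 CPM (0.00233). Further rises were in Mcam (log2 fold change 2.37), Fabp7 (1.83), Dixdc1 (1.81), C5ar2 (1.29), Mmp13 (0.98) and Maoa (0.97). Dapk2, a death-associated kinase gene, fell from 6.93 ± 1.52 to 0.937 ± 0.357 CPM (adjusted p = 0.00233), and Scn4b, a sodium channel subunit, from 15.3 ± 2.96 to 4.25 ± 0.426 CPM. Further decreases were in Nxpe4 (-2.62), Scn2b (-2.28), Mpzl2 (-1.74), Itga2b (-1.56), Bace1 (-1.47), Cyp11a1 (-1.08), Slc37a4 (-1.05) and Hmga1b (-0.99), whose reads may be shared with Hmga1.

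Genes of the mitochondrial genome were higher in cells labelled DKO. Of 13 protein-coding mitochondrial genes 6 rose and 0 fell, and 13 of 13 rose adjusted over the list alone (median 0.63, camera adjusted p = 2.45e-30, adjusted p = 0.134 with an estimated correlation). ND4 rose from 2080 ± 38.3 to 3150 ± 186 CPM and ATP6 by 0.63 on the log2 scale. Neither was called without the cells of mouse 152 (edgeR adjusted p = 0.276 and 0.262) or in the fit on all 12 libraries. The mitochondrial genome took 7.68% ± 0.343 of counts in cells labelled DKO and 5.43% ± 0.406 in WT cells (SD, n = 3; exact permutation p = 0.1, the smallest that 3 against 3 allows). Of 46 lysosome genes 2 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.000547, adjusted p = 0.546 with an estimated correlation). These were Atp6v0d2, a subunit of the proton pump that acidifies lysosomes (663 ± 22.9 to 1110 ± 94.8 CPM), and the protease Ctsl (0.63), and the median of that list went from 0.06 to -0.04 under total-count scaling. Of 37 cell cycle genes 0 were called, or 6 lower adjusted over the list alone (median -0.29, adjusted p = 8.2e-09, adjusted p = 0.546 with an estimated correlation). The list of 25 cholesterol synthesis and uptake genes was lower (median -0.18, adjusted p = 0.00105, adjusted p = 0.65 with an estimated correlation). That list ran from 1.57e-07 to 0.16 over its alternatives and lost its call without the cells labelled DKO of mouse 151 (0.16). Fasn, the fatty acid synthase gene and a member of another list, cholesterol efflux and LXR targets, fell from 47.1 ± 9.26 to 25.7 ± 2.02 CPM. It was not called without the cells of mouse 152 (edgeR adjusted p = 0.264) or in the fit on all 12 libraries.

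Markers of some other marrow cell types were lower in cells labelled DKO. Those of eosinophils (median -0.03), erythroid cells and megakaryocytes (0.07), stromal cells (-0.05) and macrophages (0.17) were not called as lists (adjusted p = 0.672, 0.888, 0.672 and 0.672). Of 7 mast cell and basophil markers 0 were called, or 6 lower adjusted over the list alone (median -1.19, adjusted p = 8.2e-09, adjusted p = 0.0571 with an estimated correlation). Mcpt8, a basophil protease, was estimated at -1.68 ± 0.32 (adjusted p = 0.056) and Prss34 at -1.26 (0.061). Of 10 B, T and NK cell markers 0 were called, or 4 lower adjusted over the list alone (median -1.08, adjusted p = 6.79e-06, adjusted p = 0.169 with an estimated correlation), with Cd79b at -2.49 ± 0.48 (0.0612). Of 15 plasma cell and myeloma transcripts 1 fell, or 8 fell and 1 rose adjusted over the list alone (median -1.15, adjusted p = 1.95e-08, adjusted p = 0.0597 with an estimated correlation). The one that fell was the immunoglobulin heavy chain Ighm, from 95.8 ± 28.2 to 36.5 ± 8.09 CPM. Of 13 MHC class II genes 0 were called, or 5 lower and 1 higher adjusted over the list alone (median -0.27, adjusted p = 0.00182, adjusted p = 0.546 with an estimated correlation). For 24 dendritic cell markers 0 were called by either adjustment (median -0.22, adjusted p = 0.00299, adjusted p = 0.546 with an estimated correlation). The dendritic list ran from 3.34e-06 to 0.111 over its alternatives, at 0.111 without the cells of mouse 46 or of mouse 153.

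In all, 53 of 13106 genes were called in cells, 35 higher and 18 lower, and the groups did not overlap for 17.3% of genes, where chance gives 10%. The count was 119 without the cells of mouse 33, 22 without mouse 42, 14 without mouse 151 and 5 without mouse 152. It was 11 with sex as a covariate, and Sidt1, Sidt2, Cadm1, Wdfy1 and Fabp4 were called under every alternative run. Total-count scaling moved the median of all genes from -0.01 to -0.109 and gave 18 higher and 20 lower.

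The called genes gathered on chromosome 9, which carries Sidt2. There were 22 of the 53 (41.5%) against 5.55% of all genes tested (odds ratio 12.4, Fisher's exact test over chromosomes, adjusted p = 3.26e-13). The mitochondrial genome was the other chromosome past the threshold, with 6 of 15 tested genes called (odds ratio 185, adjusted p = 1.67e-10). That test counts genes, which are not independent, rather than mice. Over mice the mitochondrial share of counts gave an exact permutation p = 0.1. The calls on chromosome 9 included Scn4b, Scn2b and Mpzl2, 0.8 to 0.9 Mb to the lower side of Sidt2, Bace1 at 0.1 Mb, Cadm1 1.6 Mb to the upper side, Nxpe4 at 2.2 Mb, Il18 at 4.6 Mb and Dapk2 at 20.2 Mb. The list of genes near Sidt2, which includes Sidt2, had 6 of 33 lower and 1 higher, or 11 and 1 adjusted over the list alone (adjusted p = 5.59e-14, adjusted p = 0.0295 with an estimated correlation). With Sidt2 taken out the list kept its call with the preset correlation (median -0.39, camera adjusted p = 1.07e-05), but not with an estimated correlation (0.0653). The alternatives that kept Sidt2 in the list ran lower, from 3.72e-20 to 1.94e-10. Of 22 genes near Sidt1, Sidt1 alone was called, or 2 higher adjusted over the list alone (adjusted p = 1.16e-08, adjusted p = 0.169 with an estimated correlation), and with Sidt1 taken out that list was not called (0.091, against 1.28e-09 to 4.12e-06 over the other alternatives).

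**Figure D3:**
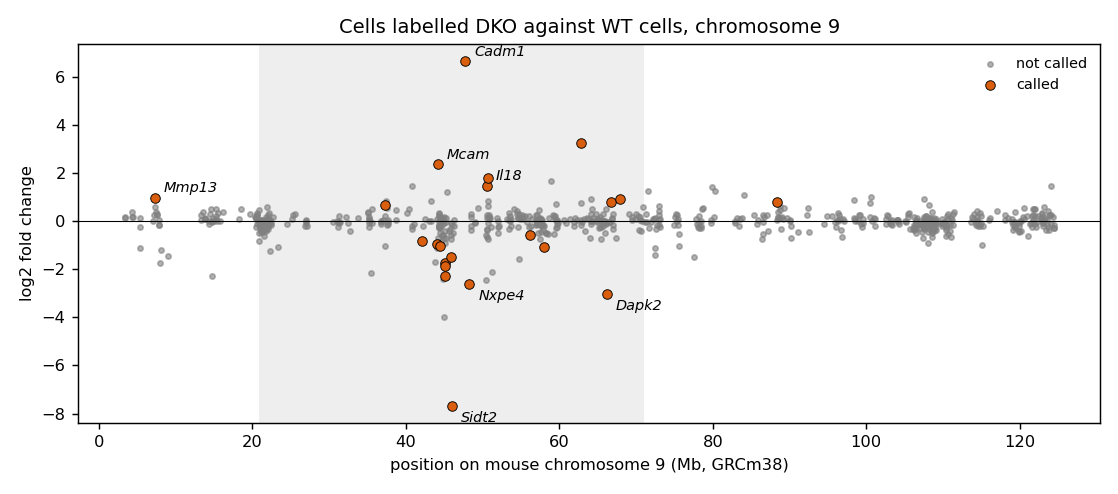
Log2 fold changes of cells labelled DKO against WT cells for the tested genes of chromosome 9 by position in Mb, with called genes in orange and the 25 Mb on either side of Sidt2 shaded. Of the called genes other than Sidt2, 19 lie in the shaded part and 2 outside it.

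In exosomes the genotype comparison called 4 genes, the targets Sidt1 and Sidt2 with Cadm1 and Wdfy1, of 12064 tested. Wdfy1 rose from 6.92 ± 2.17 CPM in WT exosomes to 82.6 ± 7.87 CPM in those labelled DKO (SD, n = 3; log2 fold change 3.53 ± 0.26, edgeR adjusted p = 0.00134). Cadm1 had 9 counts in the WT exosomes together and 510 in those labelled DKO, a ratio of 61.3 (95% counting interval 32 to 135; adjusted p = 0.0325). Cadm1 lost its call without the exosomes of mouse 42 (0.382), 151 (0.404), 152 (0.579) or 153 (0.274) and with sex as a covariate (0.0982), with a range of 9.25e-17 to 0.579 over its alternatives. The 4 genes were also called in cells, where 50 of the 12005 genes tested in both were called and 0.0167 shared genes were expected (Fisher's exact p = 2.66e-10). Sidt1 and Sidt2 are the genes that the mice were labelled by, so that p is no evidence of further shared effects. With both left out, 2 genes were shared and 0.008 were expected (Fisher's exact p = 1.57e-05). The same mice gave both kinds of library. Across the 12005 genes, which are not independent, the genotype fold changes of cells and exosomes correlated at r = 0.364.

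No other gene passed in exosomes, but groups of immune and translation genes were lower in those labelled DKO. Of 22 dendritic cell markers 0 were called, or 11 lower adjusted over the list alone (median -0.64, camera adjusted p = 2.06e-10, adjusted p = 0.0617 with an estimated correlation). Of 13 MHC class II genes 0 were called, or 7 lower adjusted over the list alone (median -0.69, adjusted p = 6.43e-07, adjusted p = 0.293 with an estimated correlation). H2-Eb1 stood at 470 ± 40.6 CPM in exosomes labelled DKO and 842 ± 173 CPM in WT exosomes (adjusted p = 0.552). Of 26 inflammatory cytokines and NF-kB targets 0 were called, or 6 lower adjusted over the list alone (median -0.29, adjusted p = 0.00168, adjusted p = 0.35 with an estimated correlation). Ccl22 stood at 173 ± 18.8 against 338 ± 42.6 CPM (adjusted p = 0.327) and Ccl17, a chemokine of the same receptor, at 396 ± 87.0 against 903 ± 148 CPM (0.481). Over the alternatives these ranged from 0.000564 to 1.0 and from 0.000694 to 0.904. Without the WT exosomes of mouse 46, Ccl22 was called (0.0411). For 85 cytosolic ribosomal proteins 0 genes were called by either adjustment (median -0.69, adjusted p = 4.14e-19, adjusted p = 0.51 with an estimated correlation), with Rplp1 at 944 ± 252 against 2170 ± 1290 CPM and Rps20 at -1.07 ± 0.39 (both adjusted p = 0.552). Without the exosomes of mouse 33 the ribosomal median was -0.22 (adjusted p = 3.85e-08), and with sex as a covariate the list lost its call (0.253, the highest of a range from 8.07e-25). Fold changes in this comparison went with gene length (Spearman 0.254 across genes). Taking off the median of genes of like length and GC content left -0.43 of the ribosomal median. Across all genes the count was 144 without the WT exosomes of mouse 46, 14 with sex as a covariate, 33 by DESeq2 and 146 by limma voom. The groups did not overlap for 14.7% of genes, where chance gives 10%, and total-count scaling moved the median of all genes from -0.008 to 0.147.

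A few abundant genes took more of the exosome counts. Fth1, the ferritin heavy chain, took 5.31% ± 0.986 of counts in WT exosomes and 6.33% ± 0.544 in those labelled DKO, against 1.23% and 1.5% in the cells (SD, n = 3). The lysozyme gene Lyz2 led in WT cells (3.00% ± 0.299) and the mitochondrial COX1 in cells labelled DKO (3.87%). The chemokine Ccl6 was among the 5 most abundant genes of both exosome groups (2.44% and 2.40%), and 1 unnamed gene, ID_319269, was among those of WT exosomes (2.43% ± 1.38). The 10 most abundant genes together took a larger share in exosomes than in cells of the same mouse in 6 of 6 mice (mean log2 ratio 0.65 ± 0.22, SD). Cytosolic ribosomal proteins did so too (0.52 ± 0.63, or 0.27 without mouse 33), both with exact permutation p = 0.0312, the smallest that 6 mice allow, and adjusted p = 0.078 over 5 classes. Neither class passed after adjustment. The mitochondrial genome was higher in exosomes of 1 of 6 mice (-0.52 ± 0.88, or -0.82 without mouse 46 and -0.31 without mouse 153, p = 0.219 by the exact test), and in the WT exosomes of mouse 46 it took 11% of counts (95% Wilson interval 11.02 to 11.05). The deposited gene length went with the exosome level in every mouse. The Spearman correlation across genes of length with the exosome-to-cell ratio was -0.378 to -0.205 in the 6 mice (median -0.304, exact sign test p = 0.0312), and that of GC content was 0.125 to 0.388. In WT mice the median log2 fold change was 0.57 in the fifth of genes with the shortest deposited length (median 976 bases) and -0.50 in the longest (6028 bases).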

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

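The list tests of the interaction were planned before the data were examined, whereas the tests of explanations, the correction of list medians for length and GC content and the counts over other splits of the mice were chosen after the results were seen. A difference between the genotypes in how exosomes differ from cells drew attention to 11 gene lists, each by the camera test of the interaction term and each with a lower exosome-to-cell change in mice labelled DKO than in WT mice. None of the 11 held with an estimated correlation, where adjusted p ran from 0.423 to 0.939.

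Translation and respiration made up the first set. The median interaction was -0.90 for cytosolic ribosomal proteins (exosome-to-cell medians 1.10 in WT and 0.13 in mice labelled DKO), -0.49 for nuclear genes of oxidative phosphorylation (0.97 and 0.37) and -0.24 for mitochondrial ribosomal proteins (0.59 and 0.29). Without the WT exosomes of mouse 33 these were -0.38, -0.25 and -0.11, and with total-count scaling -0.66, -0.26 and -0.01. Without the cells labelled DKO of mouse 152 the last was -0.16. Over their alternatives they ran from -1.09 to -0.25, from -0.67 to -0.22 and from -0.31 to -0.01. The interaction went with gene length, and the correction for length and GC content left -0.51, -0.20 and -0.06. It was -0.16 for translation factors (0.22 and -0.15, camera adjusted p = 0.0449), a list that turned to 0.08 with total-count scaling (0.329), which moved the median of all genes from 0.026 to 0.254. It also lost its call with the mouse as a block (0.0768), without the WT cells of mouse 33 (0.189), the WT exosomes of mouse 33 (0.296) or 46 (0.0614), the cells labelled DKO of mouse 151 (0.101) or 152 (0.0745), and the exosomes labelled DKO of mouse 151 (0.126), 152 (0.0726) or 153 (0.0509), within 0.0125 to 0.763 over its alternatives. The mitochondrial genome had a median of -1.04 (0.28 and -1.05), and without the WT exosomes of mouse 46 it stood at -0.17 with adjusted p = 0.768, the highest of a range from 2.01e-15. Small nuclear, nucleolar and other short non-coding RNAs had a median of -1.56 (0.90 and -0.63, camera adjusted p = 0.0158). Counts of these RNAs were few, from 93 in all in the exosomes of mouse 153 to 977 in those of mouse 46. They lost their call with the block (0.0507), without the WT cells of mouse 33 (0.0533) and without the WT exosomes of mouse 46 (0.52), within 0.000106 to 0.52.

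Immune genes made up the second set. The median interaction was -0.44 for dendritic cell markers (-1.63 in WT and -2.01 in mice labelled DKO), -0.26 for MHC class II presentation (-0.95 and -1.70), -0.10 for inflammatory cytokines and NF-kB targets (-0.15 and -0.45) and -0.61 for neutrophil markers (-0.20 and -0.71). MHC class II lost its call without the WT exosomes of mouse 46 (adjusted p = 0.0614, the highest of a range from 0.000534), and the cytokine list without the WT exosomes of mouse 42 (0.0787, the highest of a range from 0.00335) or 46 (0.0614), the WT cells of mouse 33 (0.0737) or the exosomes labelled DKO of mouse 152 (0.0539). The correction for length and GC content left -0.09 for MHC class II, -0.44 for dendritic cell markers, -0.12 for cytokines and -0.46 for neutrophil markers. The cytokine median turned to 0.13 with total-count scaling. Neutrophil markers lost theirs without the WT exosomes of mouse 33 (0.963, the highest of a range from 3.67e-07) or 42 (0.17), the WT cells of mouse 46 (0.154), the cells labelled DKO of mouse 151 (0.0614), the exosomes labelled DKO of mouse 152 (0.13) or 153 (0.372), and with the mouse as a block (0.0634). The list of long non-coding RNAs, which mixes nuclear ones with the cytoplasmic Norad, had a median of -0.62 (0.18 and -0.70). It lost its call without both libraries of mouse 33 (camera adjusted p = 0.0852, range from 0.000666).

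For single genes, all 10 splits of the 6 mice into 3 and 3 called at least the 0 genes of the real split by edgeR, and the highest count of another split was 6, with mice 33, 42 and 151 on 1 side. In the real split 776 genes had an unadjusted p under 0.05, DESeq2 called 0 and limma voom 163. With 10 splits the share can never fall below 0.1, so they are too few to decide.

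Sidt1 was read in the libraries labelled DKO and hardly in the WT libraries, against the label. An exchange of the genotype labels between WT and DKO mice would raise Sidt2 in the libraries labelled DKO, but it stood at -7.67 ± 0.23 there. A wider raised region of chromosome 16 would lift its neighbours, but the 17 tested genes within 1 Mb had a median of 0.14 (interquartile range 0.22), 0 of them were called, and the largest change was 0.46. Sex of the mice would give the WT male like counts, but its 2 libraries held 4 Sidt1 counts together against 4122 in the 6 libraries of the males labelled DKO, a ratio of 497 per total (95% counting interval 194 to 1820), which rests on 1 WT mouse. It stays open, untested, whether the reads come from a transcript of an altered allele, since which exons were read cannot be seen in counts per gene, or whether Sidt1 responds to the loss of Sidt2.

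The genotype calls of the cells gathered on chromosome 9, where 41.5% of them lay against 5.55% of tested genes (and 6 of 15 tested mitochondrial genes were called), which is more than differences spread evenly over all chromosomes would give. A candidate explanation is a linked segment around Sidt2 carried over from another strain: within chromosome 9, 19 of 335 genes within 25 Mb of Sidt2 were called against 2 of 391 farther away (odds ratio 11.7, Fisher's exact p = 2.35e-05). The limit of 25 Mb was set after the calls were seen, so the odds ratio depends in part on that choice. Within 25 Mb of Sidt1, the other targeted gene, 0 of 204 tested genes were called. A segment around Sidt2 may account for neighbours such as Cadm1 and Scn4b. With chromosome 9 left out 31 calls remained, so its share of calls does not exclude strain differences elsewhere in addition. Whether the segment acts on genes elsewhere, such as Wdfy1 and Nnt on chromosomes 1 and 13, or these differ by strain was not tested. Sex of the mice stays open, since the fit with sex as a covariate rests on 1 WT male: the ratio of fold changes with and without it had a median of 0.993 in cells (interquartile range 0.232, 22 of 22 genes with the same sign) and 0.857 in exosomes (0.513, 19 of 19). Effects of losing Sidt2 on its neighbours also stay open, and no read-level variant was examined.

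Dendritic cell marker transcripts were low in exosomes of both genotypes. A trend with gene length and GC content would leave a median near 0 once removed, but the corrected median was -1.59 in WT libraries (-1.62 before) and -1.80 in libraries labelled DKO (-2.01 before), while the lowest of 10000 random lists of like expression reached -0.73 and -0.74. A few abundant genes taking a larger share of counts (14.4% in cells and 22.5% in exosomes) would move all others by -0.14 on the log2 scale. The marker medians come from TMM scaling, which already takes such a shift off, so the value of -0.14 does not test them. Over the alternatives, total-count scaling among them, the list median stayed at -2.0 to -1.57 in WT. In libraries labelled DKO it stayed at -2.24 to -1.71. Macrophage RNA in place of dendritic cell RNA would raise macrophage markers, but 9 of 20 fell and 3 rose in WT (median -0.64) and 12 fell and 2 rose in mice labelled DKO (-0.68), although their most abundant transcript Lyz2 stood at 0.42 ± 0.14 and 0.17 ± 0.19. The macrophage list was called in neither genotype with an estimated correlation. In WT it also lost its call without the exosomes of mouse 33 (camera adjusted p = 0.0592), so a part played by macrophage RNA is not excluded. Plasma cell and myeloma transcripts, which vesicles of the X-63 supernatant might bring, showed no excess in exosomes. In WT 5 of 15 fell and 1 rose (median -0.33), and in libraries labelled DKO the median was -0.19. Which transcripts such vesicles carry was not measured, so that source stays open. Selective release of transcripts, the RNA extraction that differed between cells and vesicles, vesicles of the serum, and exosome release by part of the cells also stay open and were not tested.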

How the results depend on the processing

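The alternatives named here were planned, except those that left out both libraries of mouse 33, chromosome 9, or Sidt1 and Sidt2, those applied to the genes shared by cells and exosomes, and each mouse left out of the length relation, which were chosen after the results were seen. Of 1687 values of 109 named gene results, 1530 kept their direction and side of the threshold, 134 lost the call, 23 gained one and 0 reversed. Of 1101 values of 73 called lists, 928 were kept, 171 lost the call and 2 reversed, both in exosomes labelled DKO against WT with sex as a covariate: neutrophil markers at a median of 1.03 (past the threshold, 8.31e-09) and mast cell and basophil markers at 0.33 (0.597). Direction here is that of the list test, and in 8 further values the median changed sign while the test kept its direction. The cause was not tested for any change below unless given. Of the lost gene calls 118 were in cells labelled DKO against WT, where 24 were lost without mouse 152, 22 in the fit on all 12 libraries and 20 with sex as a covariate.

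WT exosomes against WT cells gave 4909 calls, 8316 by limma voom with quality weights, and 2284 (without the cells of mouse 46) to 5522 (without the exosomes of mouse 46). Exosomes against cells labelled DKO gave 5844 and moved by less than 1.5 times throughout. Cells labelled DKO against WT gave 53, against 202 with no filter, 192 by DESeq2, 220 by limma voom, 7 in the fit on all 12 libraries, 11 with sex as a covariate, 31 with chromosome 9 left out by construction, and 5 (without mouse 152) to 119 (without mouse 33). Exosomes labelled DKO against WT gave 4, against 20 with no filter, 33 by DESeq2, 146 by limma voom, 15 in the fit on all 12 libraries, 14 with sex as a covariate, 2 with chromosome 9 left out by construction, and 3 (without mouse 42, 151, 152 or 153) to 144 (without mouse 46). The interaction gave 0 and limma voom 163. Genes shared by cells and exosomes were 4, against 2 with Sidt1 and Sidt2 left out and 2 with chromosome 9 left out, both by construction, 12 with no filter, 14 by DESeq2, 23 by limma voom and 3 (without mouse 42) to 14 (without mouse 46).

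With an estimated correlation the lists past the threshold went from 13 to 0 in WT exosomes against cells, from 14 to 0 in those labelled DKO, from 18 to 1 in cells (genes near Sidt2, 0.0653 with Sidt2 taken out), from 17 to 0 in exosomes and from 11 to 0 in the interaction, which had 6 (without the WT exosomes of mouse 46) to 14 (without the cells labelled DKO of mouse 153). The length relation was -0.310 to -0.297 without 1 mouse, in the same direction, with 5 mice too few for a sign test below 0.0625. Shares of counts kept their direction in every alternative run.

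With the mouse as a block, 3837 genes were called in WT exosomes against cells and 6305 in those labelled DKO, and 0 in the interaction. The block ended the calls of autophagy in WT (0.0545) and of neutrophil markers (0.0634), small nuclear, nucleolar and other short non-coding RNAs (0.0507) and translation factors (0.0768) in the interaction. It changed no other call among the named results.

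Depth limits the low end: 3 counts stood for 0.093 to 0.416 CPM. In the simulated counts, 2-fold changes of genes above a floor of mean CPM were recovered at 22% for the interaction. For exosomes labelled DKO against WT the figure was 38%. Depth was not varied there, so these rates do not measure its effect.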

Other observations

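The comparison of the WT and DKO-labelled exosome changes, the list tests without Sidt1 and Sidt2, the correction of list medians for length and GC content and the counts over other splits of the libraries were chosen after the results were seen. Transcripts of secreted inflammatory mediators went both ways in exosomes. In WT mice Ccl4, a chemokine for monocytes and T cells, rose from 43.3 ± 9.55 to 192 ± 27.0 CPM (SD, n = 3) and Il1rn, the interleukin 1 receptor antagonist, by 1.36 on the log2 scale, while Ccl22 fell. In mice labelled DKO Ccl3 rose by 0.97 and Ccl5 fell by 2.70. Of 27 cytokine and NF-kB target genes 6 rose and 11 fell in WT and 8 rose and 11 fell in mice labelled DKO, also adjusted over the list alone, and the list was called in neither (camera adjusted p = 0.695 and 0.0553). In WT exosomes Abca1, a cholesterol exporter, fell from 98.8 ± 14.8 to 11.2 ± 6.15 CPM, and the log2 fold change of the integrin Itga4 was -3.13 ± 0.17. Of 25 cholesterol synthesis and uptake genes 8 fell and 4 rose there, also adjusted over the list alone, and the list was not called (adjusted p = 0.37).

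The exosome changes of the 2 genotypes, which share no library, were alike. Of 12261 genes tested in both, 1937 rose in both, where independent lists of 2376 and 2914 genes would share 564.7, and 2049 fell in both, where 2447 and 2911 would share 581.0. None was called in opposite directions, against 0 to 10 over the alternatives run, and the fold changes correlated at r = 0.851 across genes, which are not independent (0.498 to 0.866 over the alternatives run). Genes among the larger WT increases were also called in mice labelled DKO, with log2 fold changes of 3.19 for Metrn, 2.96 for Fam168b, 3.28 for Rap1gap2, 3.19 for Rnf144a and 3.03 for Rps2. Without both libraries of mouse 33 the first 4 lost their WT call (adjusted p = 0.0538 to 0.111).

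Other lists passed in the genotype comparison of cells. Of 25 heat shock and immediate early genes 0 were called, or 6 lower adjusted over the list alone (median -0.33, camera adjusted p = 0.00114, adjusted p = 0.29 with an estimated correlation). Of 19 neutrophil markers 0 were called, or 5 lower adjusted over the list alone (median -0.21, adjusted p = 0.000964, adjusted p = 0.546 with an estimated correlation). That list lost its call without the WT cells of mouse 42 (0.0847), in the fit on all 12 libraries (0.14) and with sex as a covariate (0.561), within 1.31e-06 to 0.561. In WT exosomes against cells, 12 of 31 genes near Sidt2 fell and 4 rose, or 13 fell and 5 rose adjusted over the list alone (median -0.57, adjusted p = 0.0131, adjusted p = 0.355 with an estimated correlation), and without the exosomes of mouse 46 the call was lost (0.0776, the highest of a range from 0.00827).

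Smaller shifts passed in cells as well, with 0 genes called in each list. Oxidative phosphorylation had a median of 0.13 (adjusted p = 0.000165, 0.65 with an estimated correlation, 0 called adjusted over the list alone), and lost its call without the cells of mouse 152 (0.0958, range from 3.69e-06). Cytosolic ribosomal proteins had a median of 0.13 (adjusted p = 0.000165, 0.698 with an estimated correlation, 1 higher adjusted over the list alone), and lost theirs without the cells of mouse 33 (0.263) and with sex as a covariate (0.731, range from 4.1e-07). Mitochondrial ribosomal proteins had a median of 0.06 (adjusted p = 0.00905, 0.698 with an estimated correlation, 0 alone), which turned to -0.04 with total-count scaling and lost its call without mouse 152 (0.432, range from 0.0007). MHC class I presentation had a median of -0.15 (adjusted p = 0.00561, 0.422 with an estimated correlation, 2 lower adjusted over the list alone), and lost its call without mouse 153 (0.0649, range from 0.000971). Interferon-stimulated genes had a median of -0.12 (adjusted p = 0.0182, 0.758 with an estimated correlation, 0 alone), and lost theirs without mouse 42 (0.114), 46 (0.197), 151 (0.0715) or 152 (0.646, range from 1.96e-07).

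Between exosomes of the genotypes, further lists passed with a preset correlation and none with an estimated one (adjusted p = 0.293 to 0.689). Medians were -0.38 for oxidative phosphorylation (adjusted p = 2.1e-09; 0.0657 with sex as a covariate, the highest of a range from 1.36e-14), -0.32 for cholesterol synthesis and uptake (0.00057, range 1.14e-05 to 0.0154) and -0.19 for mitochondrial ribosomal proteins (0.00158). The last lost its call without the WT exosomes of mouse 33 (0.168), those labelled DKO of mouse 151 (0.0598) and with sex as a covariate (0.364, range from 3.01e-06). The correction for length and GC content took oxidative phosphorylation (the 80 genes with a known GC content) from -0.39 to -0.13 and mitochondrial ribosomal proteins from -0.20 to 0.01. Genes near Sidt1 had a median of 0.18 (0.00158, range 0.000367 to 0.0154; of 20 Sidt1 itself rose, or 2 genes adjusted over the list alone), and genes near Sidt2 a median of -0.19 (0.00158, range 5.7e-08 to 0.023; of 27 Cadm1 rose and Sidt2 itself fell, or 2 and 5 genes adjusted over the list alone), which turned to 0.01 without the exosomes of mouse 152. With Sidt1 and Sidt2 taken out neither list was called (medians 0.16 and -0.16, adjusted p = 0.324 and 0.326).

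Other lists in these exosomes passed with 0 of their genes called. Neutrophil markers, 16 genes, had a median of -1.15 (adjusted p = 0.0158) and lost their call without the exosomes of mouse 33 (0.631) or 42 (0.0547), within 9.98e-11 to 0.631 in this direction, and mast cell and basophil markers, 4 genes, had -1.59 (0.0158) and lost theirs without mouse 33 (0.0506, within 0.00205 to 0.0506 in this direction). With sex as a covariate, which leaves 1 WT male, neutrophil markers passed in the opposite direction (median 1.03, adjusted p = 8.31e-09) and mast cell and basophil markers turned without passing (0.33, 0.597). Plasma cell and myeloma transcripts had -0.86 (0.0158; 0.146 with a filter of 1 CPM and 0.855 with sex as a covariate, range from 0.00128), and B, T and NK cell markers, 4 genes, -1.69 (0.0207; 2 lower adjusted over the list alone; 0.125 with sex as a covariate, range from 0.000905), with a median of 0.55 without mouse 33. Medians were -0.16 for the cell cycle (0.0183; 0.209 without mouse 46 and 0.304 without mouse 151, range from 0.00107), and 0.27 for sex-linked genes (0.0248), which lost their call without mouse 33 (0.0764), 151 (0.0569), 152 (0.149) or 153 (0.0977), within 1.27e-12 to 0.197, and 0.15 of the median was left after the correction. The exosomes labelled DKO came from 3 males and the WT exosomes from 2 females and 1 male. A shift of the sex-linked list was thus built into the groups and does not speak to genotype. The list of long non-coding RNAs, not all of them nuclear, had -0.68 (0.034). It lost its call without mouse 33 (0.166), 46 (0.0588), 152 (0.0699) or 153 (0.0586), within 0.00519 to 0.166. The median of the 8 with a known GC content went from -0.72 to -0.42 after the correction. MHC class I presentation had -0.09 (0.0397), turned to 0.06 with total-count scaling, and lost its call without mouse 42 (0.0547), 46 (0.209), 152 (0.113) or 153 (0.134), within 0.0123 to 0.209.

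Splits of the 6 libraries of a comparison into 3 and 3 number 10, too few for a share below 0.05. In each pairwise comparison 1 of the 10 splits, the real one, gave as many called genes. The real and the highest other count were 4909 and 0 for WT exosomes against cells, 5844 and 0 for those labelled DKO, 53 and 3 for cells, and 4 and 1 for exosomes between genotypes. In both exosome-against-cell comparisons the 3 other splits that part as many pairs of libraries of 1 mouse called 0.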
